A study of Mus musculus with 8 samples.

How the data were processed

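RNA from the striatum of 8 mice was measured on whole-transcript gene arrays, 1 array per mouse, with 2 mice in each of 4 groups. Per the labels' protocols, labelled cDNA was made from 300 ng of total RNA with a whole-transcript sense labelling assay. Per the submitters' processing notes, the arrays were processed with Affymetrix Expression Console and RMA, with no version given. RMA corrects the background, quantile-normalises the arrays and summarises the probes of each probe set on a log2 scale. The deposited table holds 1 such log2 value per probe set and array, and the values were used as they stand. No scanner files were used here, so the log2 scale rests on the processing notes and on the range of the values, with array medians between 6.02 and 6.12 and maxima between 14.3 and 14.4. Quantile normalisation gives every array nearly the same distribution, so a change in the same direction in most genes could not be seen in these values. No genome build is given in the sources used here, and no coordinates are printed.

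The platform's gene table gave 1 gene symbol for 21789 of the 35557 probe sets and several symbols for 1621, while 12147 were unnamed in it. Of the probe sets with 1 symbol, 21698 were matched to a RefSeq gene table (assembly GRCm38.p6, used for names only) by gene ID, which changed 0 symbols. Tests used probe sets with exactly 1 symbol and a mean over the 8 arrays of at least 5.25, the 25th percentile of such probe sets. This left 16342 probe sets for 14890 genes. All columns of the table belong to samples of the series.

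The labels describe the samples of a group as separate mice, and the groups were compared in 1 linear model over all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options). This left 4 residual degrees of freedom, to which the shrinkage added 2.94 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the probe sets of a comparison, at a threshold of 0.05, and every adjusted p printed for a gene comes from this model unless another fit is named. Counts at an unadjusted p under 0.05 are given beside them. By chance, 817 probe sets would lie under that value. The main comparisons were MPTP against control, each needled group against MPTP, and acupoint against non-acupoint needling. Secondary comparisons set each needled group and all MPTP-treated groups together against control, and both needled groups against MPTP. A moderated F-test over the 4 groups was set against other partitions of the arrays into 4 pairs, 100 of the 105 in all with the real one included. With 2 arrays against 2, an exact permutation test cannot give a two-sided p below 0.333, so the model across genes was used in its place.

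Of 37 gene lists, 35 had at least 3 measured genes and were tested with limma's camera, using 1 probe set per gene (the one with the highest mean) and a preset correlation between genes of 0.01. Camera asks whether the genes of a list changed more in 1 direction than the other genes did. The lists covered dopamine handling, striatal neuron classes, glial and vascular cells, neighbouring brain regions, stress pathways and gene families. Camera with the correlation estimated from the residuals, and fry, were run as alternatives. For each list, member genes were also adjusted over the list alone.

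The genes named in the text followed a rule. For each main comparison it took up to 10 higher and 10 lower genes with the smallest p-values among probe sets whose 2 groups did not overlap, leaving out gene models, unnamed clones, olfactory and vomeronasal receptors and small RNA genes. It took up to 3 in each direction for secondary comparisons, 5 for the F-test and 5 in each direction for reversal. It also took 10 fixed genes of dopamine, opioid peptide, glial, activity and choroid plexus biology, and up to 4 members of each list called in a main comparison. Groups, tests, lists, the naming rule and the alternatives, apart from those named below as added later, were fixed before the data were examined. Genes and settings chosen later are said to be so where they appear.

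The computations were tested on simulated data with known changes, using the real design and gene means. Each gene had the same spread in all groups, drawn from the fitted prior, and genes were independent. In the real arrays the spread per array was 0.357 in the MPTP group and 0.116 in controls. The rates below may thus be too high for comparisons with the MPTP group. For MPTP against control, with 200 of the 16342 probe sets changed in each of 5 simulated data sets, 93.3% of probe sets changed by 2 on the log2 scale were recovered at the adjusted threshold, 54.3% of those changed by 1 and 5.07% of those changed by 0.5. The precision of every value is limited by the number of arrays. The alternatives tried were other filters on dim probe sets, inclusion of unnamed probe sets, trend and robust shrinkage, other normalisations of the deposited values, array weights, a fit on only the groups compared, the mouse number as a block, and leaving out each array in turn. After seeing the data, 2 settings were added: leaving out both arrays with the highest mean of the thalamus, septum and pallidum markers, and that mean as a covariate. Python 3.11.15 and matplotlib 3.10.9 were used to draw the plots.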

Results

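Gene expression was measured in the striatum of 8 male C57BL/6 mice, an inbred laboratory strain, in 4 groups of 2 mice. The striatum is the forebrain nucleus that receives the dopamine axons of the substantia nigra, and MPTP is a neurotoxin that damages those axons and is used to model Parkinson's disease in mice. The animals were 6 weeks old. Control mice received saline, and the other groups received MPTP at 20 mg/kg every 24 h for 4 weeks. Among these, the MPTP group had no needling. The acupoint group was also needled at GB34 (3 mm deep) and LR3 (1 mm deep), and the non-acupoint group at the hips (3 mm deep), in 14 sessions 48 h apart. The comparisons ask what MPTP changed in the striatum, whether needling moved it, and whether the site of needling mattered. The median log2 value of an array lay between 6.02 and 6.12, and the number of arrays limits the precision of every value below.

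The arrays differed in the levels of marker genes of brain tissues and cell types, within groups as well as between them. MPTP mouse 1 stood apart. Relative to the mean of the controls, its genes of dopamine receptors and striatal signalling averaged -1.37 on the log2 scale, against 0.26 in MPTP mouse 2. Its markers of thalamus, septum and pallidum, which border the striatum, averaged 1.49, against -0.65 in MPTP mouse 2. Non-acupoint mouse 2 had the next highest mean of these markers, at 1.15, with -0.50 for the striatal signalling genes. Markers of the choroid plexus, the tissue that secretes cerebrospinal fluid, were high in 4 arrays: 2.15 in MPTP mouse 1, 2.32 in acupoint mouse 1, and 2.10 and 2.82 in non-acupoint mice 1 and 2. In the remaining MPTP and acupoint mice they averaged -0.18 and 0.13. The transthyretin gene Ttr, the main secreted product of that tissue, had log2 values of 8.63 and 8.88 in the controls and 13.39 and 8.12 in the MPTP mice. The first principal component held 55.8% of the variance, with a score of 42.3 for MPTP mouse 1 and -20.1 for MPTP mouse 2. The correlation between the arrays of a group was 0.995 in controls, 0.989 in each needled group and 0.950 in the MPTP group. In the MPTP group, 5.07% of probe sets differed by 1 or more on the log2 scale, against 0.00612% in controls.

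**Figure D1:**
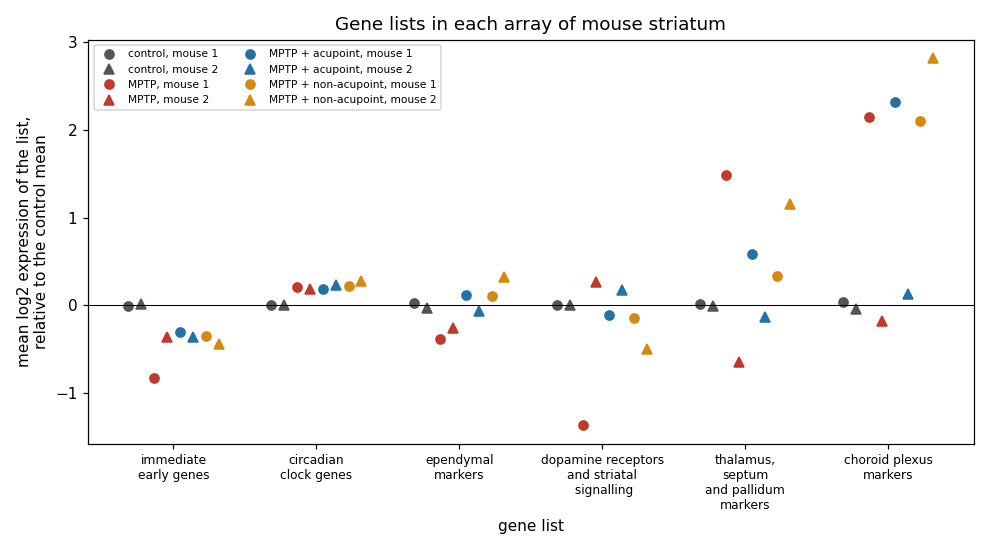
Mean log2 value of the genes of selected lists in each of the 8 arrays, relative to the mean of the controls, with 1 point per array. Immediate early genes lie below the controls in every MPTP-treated array, while striatal signalling genes are at -1.37 in MPTP mouse 1 and 0.26 in MPTP mouse 2.

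The first comparison asks what MPTP changed. Several genes that neurons switch on when they are active had lower means in MPTP-treated striatum than in controls, but none passed on its own, and their list was called only with a preset correlation (adjusted p = 0.25 with an estimated correlation). Npas4, an activity-dependent transcription factor of neurons, had a mean log2 value of 7.94 in controls and 6.25 in MPTP mice, a change of -1.69 (SE 0.19, adjusted p = 0.46). Arc, a synaptic plasticity protein made on activity, went from 9.39 to 7.96, a change of -1.42 (SE 0.22, adjusted p = 0.93), and Fos changed by -0.82 (SE 0.18). Sgk1, a kinase induced by glucocorticoids, was higher, at 9.81 against 8.96, a change of 0.84 (SE 0.13, adjusted p = 0.93). No single gene passed the adjusted threshold: limma called 0 of 16342 probe sets, with 652 at an unadjusted p under 0.05, of which 344 were higher and 308 lower, where chance gives 817.

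Immediate early genes, the first genes transcribed after a stimulus, fell as a group, by camera with a preset correlation. Of 25 measured, 20 were lower, 12 had an unadjusted p under 0.05 and 10 passed when adjusted over the list alone. Their mean change was -0.60 and the list's adjusted p was 2.3e-14, with adjusted p = 0.25 with an estimated correlation. Beside Npas4 and Arc, Btg2, an antiproliferative gene, changed by -0.72, and Ccn1, a matricellular protein, by -0.67 (SE 0.14). The list mean was -0.83 in MPTP mouse 1 and -0.36 in MPTP mouse 2, and without mouse 1 the list kept its call (-0.36, adjusted p = 5e-12). With the thalamus marker mean as a covariate, a setting chosen after seeing the data, Npas4 and Arc both passed the adjusted threshold (-1.60 and -1.30, adjusted p = 0.023 for each).

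Ependymal markers, genes of the ciliated cells that line the ventricles, also fell as a group, with 9 of 10 lower. Their mean change was -0.32 (adjusted p = 9.7e-06; adjusted p = 0.35 with an estimated correlation), and 3 passed when adjusted over the list alone. Tmem212 changed by -0.75, Ccdc153 by -0.59, the adenylate kinase Ak7 by -0.57 and Rarres2, which encodes chemerin, by -0.51. Small nucleolar RNA genes, which guide the modification of ribosomal RNA, were lower in 22 of 31 cases, with a mean of -0.17 (adjusted p = 9.7e-06; adjusted p = 0.25 with an estimated correlation). Gas5, the host gene of several of them, changed by -1.02 (SE 0.18). Glucocorticoid-responsive genes rose as a group, with 14 of 16 higher and a mean of 0.20 (adjusted p = 0.0035; adjusted p = 0.25 with an estimated correlation). The list mean was 0.28 in MPTP mouse 1 and 0.13 in MPTP mouse 2. Besides Sgk1, Zbtb16, a transcription factor, changed by 0.53, Arrdc2 by 0.28 and the lipid droplet gene Plin4 by 0.26. Circadian clock genes rose as well, with 14 of 16 higher and a mean of 0.20 (adjusted p = 0.0022; adjusted p = 0.25 with an estimated correlation). Ciart, a repressor of the clock, changed by 0.61, and the clock repressors Bhlhe41 and Nr1d2 by 0.41 and 0.39. The clock output factor Hlf changed by 0.40. The circadian call ended without MPTP mouse 2 (0.21, adjusted p = 0.13), while the ependymal, small nucleolar RNA, glucocorticoid and immediate early lists kept theirs whichever array was left out. Of the genes named here, those that moved most in these fits had changes closest to 0 of 0.15 (Zbtb16), 0.16 (Hlf), 0.11 (Arrdc2), 0.19 (Nr1d2), 0.38 (Ciart), -0.20 (Ak7) and -0.48 (Tmem212).

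For the genes of striatal neurons, the direction depended on which MPTP mouse was counted. Genes of dopamine receptors and striatal signalling averaged -0.55, with 14 of 16 lower (adjusted p = 0.0022; adjusted p = 0.72 with an estimated correlation), and 0 had an unadjusted p under 0.05 by limma. Markers of direct-pathway medium spiny neurons, the projection neurons that carry the D1 receptor, averaged -0.55, with all 8 lower (adjusted p = 0.017; adjusted p = 0.72 with an estimated correlation). Without MPTP mouse 1 these lists turned to 0.26 (adjusted p = 0.001) and 0.32 (adjusted p = 0.0072). Drd1, the D1 dopamine receptor, had log2 values of 10.29 and 10.32 in controls and 7.93 and 10.68 in the MPTP mice. Its change was -1.01 (SE 0.76), and that of Drd2, the D2 receptor, was -0.73 (SE 0.67). The neuropeptide genes Penk, Tac1 and Pdyn changed by -0.82 (SE 0.55), -1.07 (SE 0.81) and -0.56 (SE 0.67). Ppp1r1b, which encodes the dopamine signalling protein DARPP-32, changed by -1.06 (SE 0.74), and the signalling regulators Rgs9 and Rgs2 by -1.02 and -0.71. Interneuron markers averaged -0.21 (adjusted p = 0.03; adjusted p = 0.72 with an estimated correlation), among them the choline transporter Slc5a7 at -1.15 and the transcription factor Lhx8 at -0.72. Microglia markers averaged -0.16 (adjusted p = 0.0035; adjusted p = 0.72 with an estimated correlation), with Aif1 and the fractalkine receptor Cx3cr1 at -0.33 each. When 1 array was left out, Lhx8 went as far as -0.26, Aif1 as -0.16 and Cx3cr1 as -0.06. Without MPTP mouse 1 the interneuron and microglia lists stood at 0.02 (adjusted p = 0.33) and 0.10 (adjusted p = 0.11), and without control mouse 1 the interneuron list stood at -0.20 (adjusted p = 0.11). Choroid plexus markers averaged 0.98 (adjusted p = 0.0068; adjusted p = 0.72 with an estimated correlation), with Kcnj13, a potassium channel, at 2.20 (SE 1.86) and Ttr at 2.00 (SE 1.69). Without MPTP mouse 1 their mean was -0.18. With the thalamus marker mean as a covariate, chosen after seeing the data, 9 of the 10 lists called in this comparison kept call and direction. The striatal signalling and direct-pathway lists were among them. Only the microglia call ended (-0.07, adjusted p = 0.076 by camera).

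Genes of dopamine synthesis, transport and breakdown did not pass (12 genes, mean 0.16, adjusted p = 0.28). Th, the rate-limiting enzyme of dopamine synthesis, changed by 0.11 (SE 0.27), and Slc6a3, the dopamine transporter, by 0.60 (SE 0.37), or as little as 0.18 with 1 array left out. The cell bodies of the dopamine neurons lie outside the striatum. Indirect-pathway markers averaged -0.50 (adjusted p = 0.061), cortical neuron markers -0.21 (adjusted p = 0.11), thalamus, septum and pallidum markers 0.42 (adjusted p = 0.58) and opioid peptides and receptors -0.24 (adjusted p = 0.41). Astrocyte markers averaged -0.01 (adjusted p = 0.6) and reactive astrocyte genes -0.06 (adjusted p = 0.13), and the astrocyte filament gene Gfap changed by -0.21 (SE 0.26). Inflammatory mediators averaged -0.06 (adjusted p = 0.44), interferon-stimulated genes 0.04 (adjusted p = 0.85), oligodendrocyte and myelin genes 0.05 (adjusted p = 0.8), oligodendrocyte precursor markers -0.06 (adjusted p = 0.11) and endothelial and pericyte markers 0.07 (adjusted p = 0.26). Complex I subunits, the respiratory enzyme that the active metabolite of MPTP inhibits, averaged 0.07 (adjusted p = 0.1). Oxidative stress genes averaged 0.07 (adjusted p = 0.44), apoptosis genes 0.09 (adjusted p = 0.28), endoplasmic reticulum stress genes -0.03 (adjusted p = 0.44) and heat shock proteins -0.05 (adjusted p = 0.26). Familial parkinsonism genes averaged 0.09 (adjusted p = 0.16), neurotrophic genes -0.02 (adjusted p = 0.3), proteasome genes 0.05 (adjusted p = 0.44) and histone genes -0.02 (adjusted p = 0.44). GABA and glutamate genes averaged 0.02, with a test direction below 0 (adjusted p = 0.91), ribosomal protein genes -0.03 (adjusted p = 0.11), olfactory receptor genes -0.04 (adjusted p = 0.26) and sex-linked genes -0.01 (adjusted p = 0.83).

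Other genes with the smallest p-values and no overlap between the groups were Mul1, a mitochondrial ubiquitin ligase (0.60, SE 0.10), Acyp1 (0.72, SE 0.14), Tns2 (0.68), Bloc1s3 (0.56), the mitochondrial ribosomal protein gene Mrps27 (0.52), Mpp7 (0.51), the proteasome subunit gene Psmb5 (0.49), the signalling adaptor Traf2 (0.45) and Fras1 (0.43). On the lower side were Glp1r, the receptor of glucagon-like peptide 1 (-1.70, SE 0.21, adjusted p = 0.53), Avpr1a, a vasopressin receptor (-0.92, SE 0.11, adjusted p = 0.46), the chemokine gene Cxcl5 (-1.37, SE 0.23), Tmem178 (-0.84), Tceal6 (-0.77) and Ccdc81 (-0.48). Of all probe sets, 29.3% had groups that did not overlap, where chance gives 33.3%. The shares were 27.3%, 33.1% and 38.5% in the other main comparisons in order, and 33.9% and 49.5% for acupoint and non-acupoint needling against control. The count of 0 calls became 1607 without MPTP mouse 2, which leaves MPTP mouse 1 alone in its group, and stayed at 0 without MPTP mouse 1.

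The second comparison asks what acupoint needling changed in MPTP-treated mice. Several genes that were low in the MPTP group had values closer to those of controls in the acupoint group. They were picked by values of the same MPTP arrays from which this change starts, so some return toward controls comes from the choice alone. MPTP mice 1 and 2 were also low in ependymal markers (-0.39 and -0.26). Their means of 3 lateral septum markers were -0.41 and -0.48, with a standard error over genes of 0.75 in MPTP mouse 1. The design does not separate a difference in dissection from an effect of needling on these genes. At an unadjusted p under 0.05, limma found 89 probe sets lower after MPTP and then higher. Simulated unchanged groups, with genes drawn independently, gave means of 117.4 with 1 spread for all groups and 563.5 with the spread of each group. Glp1r, with a mean of 7.35 against 7.42 in controls, was higher than in MPTP mice by 1.63 (SE 0.21), Cxcl5 by 1.20 (SE 0.23), Gas5 by 0.81 and Avpr1a by 0.64, each with an adjusted p of 0.90. Eomes, a T-box transcription factor, was higher by 0.81 (SE 0.14). Npas4 and Arc were higher by 0.53 and 0.69, but by as little as 0.23 and 0.33 with 1 array left out. Limma called 0 genes, with 588 at an unadjusted p under 0.05, of which 170 were higher and 418 lower.

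Ependymal markers rose as a group, with 9 of 10 higher and a mean of 0.35 (adjusted p = 1.2e-07; adjusted p = 0.52 with an estimated correlation), and 3 passed when adjusted over the list alone. Tmem212 changed by 0.75, Ak7 by 0.74, the dynein light chain Dynlrb2 by 0.51 and Rarres2 by 0.41. With 1 array left out, Ak7 went as far as 0.37 and Tmem212 as 0.48. The cilium gene Rsph4a, outside that list, changed by 0.71. Small nucleolar RNA genes rose too, with 22 of 31 higher, a mean of 0.23 and 6 that passed when adjusted over the list alone (adjusted p = 7.7e-07; adjusted p = 0.52 with an estimated correlation). Of the 13 lists called here, these and the immediate early genes kept their calls whichever array was left out. Without acupoint mouse 2 the number of lists called was 7.

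The other calls ended or turned in at least 1 of these fits. With the thalamus marker covariate, chosen after seeing the data, 9 of the 13 lists kept call and direction, the striatal signalling list among them. Striatal signalling genes averaged 0.59, with 15 of 16 higher (adjusted p = 9.1e-05; adjusted p = 0.67 with an estimated correlation), but -0.23 without MPTP mouse 1 (adjusted p = 0.02). Direct-pathway markers averaged 0.59 (adjusted p = 0.012; adjusted p = 0.67 with an estimated correlation) and turned to -0.28 without that array (adjusted p = 0.019). Indirect-pathway markers averaged 0.50 (adjusted p = 0.017; adjusted p = 0.67 with an estimated correlation) and stood at -0.23 without it (adjusted p = 0.13). Drd1 changed by 0.98, Drd2 by 0.84, Penk by 0.89, Tac1 by 1.27 and Pdyn by 0.80. Th changed by 0.12, Slc6a3 by -0.13, Gfap by 0.20 and Ttr by 0.95. The direction of each of these genes turned when 1 array was left out. Fos changed by -0.02 (SE 0.18), and by 0.01 with each array centred on its median, 0.003 after quantile normalisation and 0.015 with the thalamus marker covariate. Immediate early genes averaged 0.26, with 14 of 25 higher (adjusted p = 0.00017; adjusted p = 0.62 with an estimated correlation), and 0.03 without MPTP mouse 1 (adjusted p = 0.05, under the threshold before rounding). Nr4a3 and Fosb, transcription factors of that list, changed by 0.73 and 0.79, but by as little as 0.20 and 0.19 with 1 array left out. Microglia markers averaged 0.17 with all 16 higher (adjusted p = 0.00022; adjusted p = 0.67 with an estimated correlation), and -0.09 without MPTP mouse 1 (adjusted p = 0.24). Interneuron markers averaged 0.27 (adjusted p = 0.0081; adjusted p = 0.67 with an estimated correlation), and 0.03 without that array (adjusted p = 0.41).

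Endothelial and pericyte markers fell as a group, with 13 of 15 lower and a mean of -0.15 (adjusted p = 0.012; adjusted p = 0.67 with an estimated correlation). The tight junction gene Cldn5 and the matrix protein gene Vtn changed by -0.39 each, and the vascular receptors Tek and Flt1 by -0.30 and -0.22. Proteasome genes averaged -0.10, with 20 of 25 lower (adjusted p = 0.047; adjusted p = 0.62 with an estimated correlation) and Psmb5 at -0.39. Reactive astrocyte genes averaged 0.10 (adjusted p = 0.02; adjusted p = 0.67 with an estimated correlation), with the surface protein gene Cd109 at 0.40, S100a10 at 0.25 and the filament gene Vim at 0.20. With 1 array left out, Cd109 went as far as 0.14, Vim as 0.13 and Flt1 as -0.13. Ribosomal protein genes averaged 0.04 (adjusted p = 0.0086; adjusted p = 0.72 with an estimated correlation) and olfactory receptor genes 0.07 (adjusted p = 0.017; adjusted p = 0.8 with an estimated correlation). The endothelial call ended without MPTP mouse 1 (-0.09, adjusted p = 0.29), MPTP mouse 2 (-0.21, adjusted p = 0.063) or acupoint mouse 1 (-0.13, adjusted p = 0.21), and the proteasome call ended whichever array was left out, with adjusted p between 0.057 and 0.32 and a mean that stayed between -0.11 and -0.09. The reactive astrocyte and olfactory receptor calls ended without MPTP mouse 2 (0.03 for each, adjusted p = 0.55 and 0.52), and the ribosomal list stood at -0.03 without MPTP mouse 1 (adjusted p = 0.88). Other genes by the naming rule were Dnajb6, a co-chaperone (0.61), the RNA helicase Ddx54 (0.56), Ccdc81 (0.54) and Nudt10 (0.50). On the lower side were Fam151a and the small GTPase Rhov (-0.58 each), Dus2, a tRNA-modifying enzyme (-0.57), Macrod1 (-0.53), Xkr4 (-0.52), Degs2 and Nr2c2ap (-0.47 each), the small GTPase Rnd2 (-0.42), Msmp (-0.41) and Egfem1 (-0.39). The count of 0 genes became 1453 without MPTP mouse 2.

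**Figure D2:**
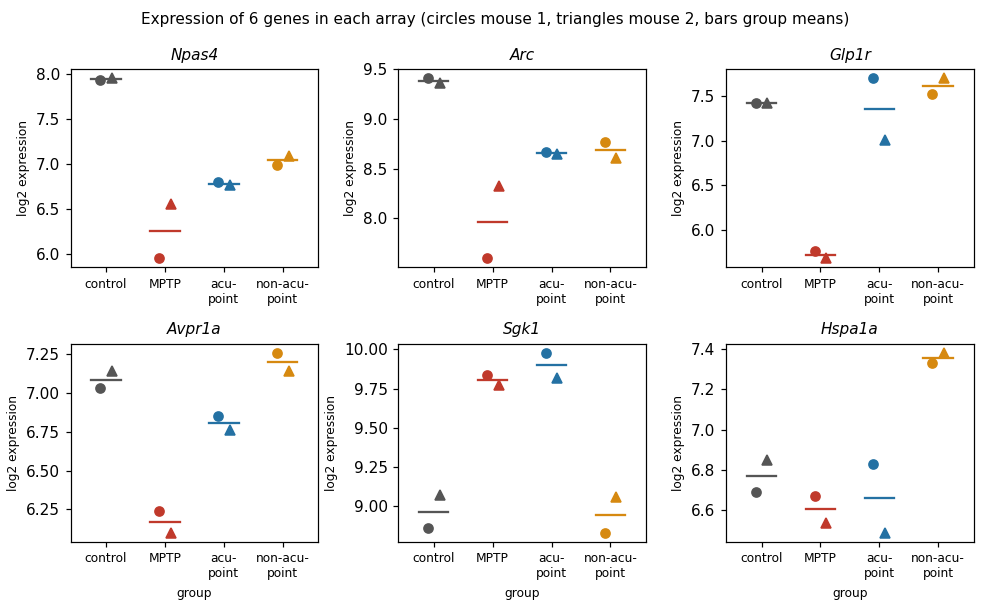
Log2 values of Npas4, Arc, Glp1r, Avpr1a, Sgk1 and Hspa1a in each of the 8 arrays, by group, with 1 point per array and the group means. Glp1r is at 5.76 and 5.68 in the MPTP mice and at 7.01 or above in every other array.

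The third comparison asks the same of needling at the hips. Among the genes with the smallest p-values were again Glp1r, higher than in MPTP mice by 1.89 (SE 0.21), Avpr1a by 1.04 (SE 0.11), Eomes by 1.23 (SE 0.14) and Cxcl5 by 1.68, each with an adjusted p of 0.34. With the thalamus marker covariate, a setting chosen after seeing the data, these were among 12 genes called by limma (adjusted p = 0.04 for each of them). Tnnt1, a thalamus marker outside the list behind the covariate, was also among the 12 (-1.03, adjusted p = 0.05, under the threshold before rounding). The covariate may thus not remove all of the tissue difference. The limits given for these genes in the second comparison hold here too. Scn9a, a voltage-gated sodium channel, was higher by 1.03 (SE 0.14) and Rsph4a by 1.08. Sgk1, high in the MPTP group, was lower by 0.86 on the log2 scale (-0.86, SE 0.13, adjusted p = 0.39). Limma called 0 genes, with 1076 at an unadjusted p under 0.05, of which 574 were higher and 502 lower.

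Ependymal markers rose as a group, with a mean of 0.53 and 8 of 10 higher, and 7 passed when adjusted over the list alone (adjusted p = 1.4e-07; adjusted p = 0.45 with an estimated correlation). Ak7 changed by 1.13, Tmem212 by 1.06, Rarres2 by 0.71 and Dynlrb2 by 0.67. This was the 1 list of 12 called that kept its call whichever array was left out. Heat shock proteins, the chaperones of protein folding, rose as a group, with 10 of 11 higher and a mean of 0.25 (adjusted p = 0.00022; adjusted p = 0.68 with an estimated correlation). Hspa1a, which encodes the inducible HSP70, changed by 0.75 (SE 0.14), from 6.61 to 7.35. Its co-chaperones Dnajb1 and Bag3 changed by 0.44 and 0.42, and the small heat shock protein gene Hspb1 by 0.27. Reactive astrocyte genes rose, with 11 of 13 higher and a mean of 0.27 (adjusted p = 0.00028; adjusted p = 0.45 with an estimated correlation). The protease inhibitor Serpina3n changed by 0.55, Cd109 by 0.52, S100a10 by 0.38 and Vim by 0.31. With 1 array left out, Bag3 went as far as 0.23, Hspb1 as 0.06, Serpina3n as 0.35 and Cd109 as 0.26. Without MPTP mouse 2 the heat shock list stood at 0.17 (adjusted p = 0.14) and the reactive astrocyte list at 0.20 (adjusted p = 0.074).

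Choroid plexus markers averaged 1.48 with all 14 higher (adjusted p = 1.8e-05; adjusted p = 0.68 with an estimated correlation), among them the channel gene Clic6 at 1.24, and 0.32 without MPTP mouse 2 (adjusted p = 0.43). Complex I subunits fell as a group, with 32 of 35 lower and a mean of -0.14 (adjusted p = 1.8e-05; adjusted p = 0.68 with an estimated correlation), Ndufa8 and Ndufa2 changing by -0.22 each. Without MPTP mouse 1 their mean was -0.07 (adjusted p = 0.1). Oligodendrocyte precursor markers averaged 0.14 (adjusted p = 0.025; adjusted p = 0.68 with an estimated correlation), with the receptor Gpr17 at 0.37 and the transcription factor Sox6 at 0.33, and 0.06 without MPTP mouse 2 (adjusted p = 0.52). Histone genes averaged -0.14 (adjusted p = 0.034; adjusted p = 0.72 with an estimated correlation), with H2bc14 at -0.48, and -0.01 without MPTP mouse 2 (adjusted p = 0.94). Ribosomal protein genes averaged -0.08 (adjusted p = 0.013; adjusted p = 0.72 with an estimated correlation), and -0.01 without MPTP mouse 2 (adjusted p = 0.99). Proteasome genes averaged -0.10 (adjusted p = 0.013; adjusted p = 0.45 with an estimated correlation), with a call that ended without MPTP mouse 1 (adjusted p = 0.065), MPTP mouse 2 (adjusted p = 0.14) or non-acupoint mouse 1 (adjusted p = 0.053) while the mean stayed at -0.10. Olfactory receptor genes averaged -0.10 (adjusted p = 0.013; adjusted p = 0.75 with an estimated correlation), and 0.01 without non-acupoint mouse 2 (adjusted p = 0.91). Immediate early genes averaged 0.20, with Npas4 at 0.79 and Arc at 0.72 (as little as 0.48 and 0.36 with 1 array left out), and interneuron markers 0.33 (adjusted p = 0.042 for each; adjusted p = 0.68 with an estimated correlation for each). Without MPTP mouse 1 these stood at -0.03 (adjusted p = 0.99) and 0.09 (adjusted p = 0.38).

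Other genes by the naming rule were Prokr2, a prokineticin receptor (0.99), Spata18, a mitochondrial quality control gene (0.92), Gabre, a GABA receptor subunit (0.80), and Zfp36l1, an RNA-binding protein that destabilises messenger RNA (0.62). On the lower side were Gabrd, another GABA receptor subunit (-0.67), Batf2 and the histone gene H2bc18 (-0.52 each), Klhdc4 and Yju2 (-0.47 each), Fsd1 and the complex III assembly factor Uqcc3 (-0.46 each), and Haghl and Mul1 (-0.44 each). The count of 0 genes became 794 without MPTP mouse 2.

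The fourth comparison sets the needling sites against each other. Sgk1 was higher after acupoint than after non-acupoint needling, with a mean of 9.90 against 8.95, a difference of 0.95 (SE 0.13, adjusted p = 0.96). Hspa1a was lower (-0.69, SE 0.14), as were Scn9a (-0.80), the death ligand Tnfsf10 (-0.60), the GABA receptor subunit Gabrq (-0.80) and Prokr2 (-0.60). Limma called 0 genes, with 526 at an unadjusted p under 0.05, of which 179 were higher and 347 lower. The model shares 1 spread over the 4 groups, and the MPTP arrays, not compared here, raise it. The spread per array was 0.357 in the MPTP group, 0.168 in the acupoint group and 0.170 in the non-acupoint group. A count below chance therefore does not show that the sites were alike.

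Heat shock proteins were lower as a group in the acupoint group, with all 11 lower and a mean of -0.24 (adjusted p = 0.00034; adjusted p = 0.67 with an estimated correlation). Dnajb1 differed by -0.36, Hspb1 by -0.34 and Bag3 by -0.33. Ribosomal protein genes were higher in 48 of 53 cases, with a mean of 0.12 (adjusted p = 6.2e-10), olfactory receptor genes in 54 of 66, with a mean of 0.17 (adjusted p = 2.3e-09), and histone genes in 13 of 17, with a mean of 0.12 (adjusted p = 0.00034). For each of these 3 lists the result was adjusted p = 0.67 with an estimated correlation. These and the heat shock list kept their calls whichever array was left out, but their sizes moved. The lowest mean of the olfactory list was 0.06, without non-acupoint mouse 2. Without acupoint mouse 2 the histone list stood at 0.05, the heat shock list at -0.14 and the ribosomal list at 0.09. Olfactory receptor genes averaged 0.10 and -0.10 in the controls. The other 9 lists called did not. Choroid plexus markers averaged -1.24 with all 14 lower (adjusted p = 0.00034; adjusted p = 0.67 with an estimated correlation), and -0.14 without acupoint mouse 2 (adjusted p = 0.85). Striatal signalling genes averaged 0.35 (adjusted p = 0.0015; adjusted p = 0.67 with an estimated correlation), and -0.01 with the thalamus marker covariate (adjusted p = 0.55). Microglia markers averaged 0.12 (adjusted p = 0.0036; adjusted p = 0.67 with an estimated correlation), and 0.01 with that covariate (adjusted p = 0.43). Small nucleolar RNA genes averaged 0.11 (adjusted p = 0.0012), complex I subunits 0.06 (adjusted p = 0.0012), glucocorticoid-responsive genes 0.08 (adjusted p = 0.038), reactive astrocyte genes -0.17 (adjusted p = 0.043), and oligodendrocyte precursor and ependymal markers -0.15 and -0.19 (adjusted p = 0.047 for each), all with adjusted p = 0.67 with an estimated correlation. Without non-acupoint mouse 2 the calls of the striatal signalling (0.17, adjusted p = 0.05), small nucleolar RNA (0.05, adjusted p = 0.094), reactive astrocyte (-0.07, adjusted p = 0.69), precursor (-0.09, adjusted p = 0.45) and ependymal (-0.08, adjusted p = 0.69) lists ended. Without non-acupoint mouse 1 those of the complex I (0.05, adjusted p = 0.089), glucocorticoid (0.07, adjusted p = 0.12) and microglia (0.09, adjusted p = 0.12) lists did.

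Other genes by the naming rule were the chemokine gene Ccl17 (0.63), Krtap10-4 (0.53), Aldoart1 (0.51), Cand2 and Ccdc110 (0.48 each), the transporter gene Abcc3 (0.46), the ATP synthase gene Atp5md (0.43), the histone gene H4f16 (0.35) and the ribosomal protein gene Rpl34 (0.34). On the lower side were Zscan29 (-0.59), Zfp36l1 and the caspase gene Casp6 (-0.42 each), Cryzl2 (-0.40) and Lpp (-0.38).

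Whether needling reversed the MPTP change was measured as the correlation, across genes, between the change from control to MPTP and that from MPTP to needling. Genes are not independent replicates, and the MPTP arrays enter both changes with opposite signs, so unchanged groups would give a negative value too. For acupoint needling the correlation was -0.76 and for non-acupoint needling -0.46, against -0.50 in 100 simulations of unchanged groups with 1 spread for all groups. The spread per array was 0.357 in the MPTP group and 0.116 in controls, and in simulations added after the data were seen, with the spread of each group, unchanged groups gave -0.86 for both. Neither correlation was more negative than that, though the acupoint value was more negative than with 1 spread. The covariances were -0.0348 and -0.0223, against -0.0638 and -0.0636. With a different MPTP mouse in each change, so that no array was shared, the correlations were positive: 0.40 and 0.30 for acupoint needling, and 0.53 and 0.19 for non-acupoint needling. The MPTP mice lay on opposite sides of the controls on the first principal component (42.3 and -20.1, against -11.4 and -10.9). This can make these correlations positive even if needling changed nothing, so their sign is no evidence against reversal. At an unadjusted p under 0.05, 91 probe sets were higher after MPTP and lower after acupoint needling, and 89 were lower and then higher. For non-acupoint needling the counts were 85 and 139. Unchanged groups with 1 spread gave 118.4 and 117.4 such probe sets for acupoint and 117 and 118.5 for non-acupoint needling. With the spread of each group they gave 572 and 563.5, and 568.4 and 563.7. The count of 139 thus lies above the first simulation and below the second, and the other counts lie below both. Both simulations drew each gene independently, and only means over the 100 runs were kept. In the data the first principal component held 55.8% of the variance, so unchanged groups of such mice could give other counts and correlations. The simulations therefore neither show nor exclude a reversal. The genes with the clearest opposite changes after acupoint needling were Glp1r, Avpr1a, Cxcl5, Ccdc81 and Rsph4a, lower and then higher, and Degs2, Acyp1, Mul1, Mrps27 and Tekt5, higher and then lower. Tekt5, a cilium gene, changed by 0.59 and then by -0.53, and Rsph4a by -0.70 and then by 0.71. The size for Tekt5 depended on the mouse, with log2 values of 7.96 and 7.54 in the MPTP mice and 7.19 and 7.13 in controls. The 2 sets of changes on needling had a correlation of 0.62 across genes, against 0.50 simulated with 1 spread and 0.81 with the spread of each group.

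Set against controls, all MPTP-treated mice together had lower immediate early genes, with 22 of 25 lower and a mean of -0.44 (adjusted p = 7.4e-14; adjusted p = 0.09 with an estimated correlation), 7 of them past the threshold when adjusted over the list alone. Circadian clock genes were higher, with a mean of 0.22 (adjusted p = 5.7e-07; adjusted p = 0.09 with an estimated correlation), and passed fry (adjusted p = 0.017). Glucocorticoid-responsive genes were higher, with a mean of 0.21 (adjusted p = 2.9e-05; adjusted p = 0.09 with an estimated correlation). Choroid plexus markers averaged 1.56 (adjusted p = 7.6e-10; adjusted p = 0.75 with an estimated correlation) and cortical neuron markers -0.33 (adjusted p = 0.0031; adjusted p = 0.47 with an estimated correlation). The other calls were ribosomal protein genes at -0.04 (adjusted p = 0.037; adjusted p = 0.96 with an estimated correlation) and small nucleolar RNA genes at -0.05 (adjusted p = 0.029; adjusted p = 0.75 with an estimated correlation), and both calls ended when any of several arrays was left out, at means between -0.05 and -0.02, and of -0.03. Npas4 was lower (-1.25, SE 0.15), as were Btg2 (-0.70) and Tmem178 (-0.74), and Mpp7 (0.64, SE 0.09), Cables1 (0.69) and the centrosome gene Cep350 (0.54) were higher. Limma called 0 genes, with 552 at an unadjusted p under 0.05, and 70 were called without MPTP mouse 2.

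The acupoint group alone differed from controls in immediate early genes (-0.33, adjusted p = 6.5e-08; adjusted p = 0.26 with an estimated correlation), with Npas4 at -1.16, Btg2 at -0.79 and the phosphatase gene Dusp1 at -0.73. Glucocorticoid-responsive and circadian genes averaged 0.25 and 0.20 (adjusted p = 6.1e-08 and 6.5e-08; adjusted p = 0.058 with an estimated correlation for each), with Sgk1 at 0.94, and cortical neuron markers averaged -0.42 (adjusted p = 0.00094; adjusted p = 0.37 with an estimated correlation). Choroid plexus markers averaged 1.22 with all 14 higher (adjusted p = 6.6e-08; adjusted p = 0.98 with an estimated correlation), and 0.13 without acupoint mouse 1 (adjusted p = 0.6). Mpp7 and Cables1 were higher by 0.74 and 0.63. In the non-acupoint group, immediate early genes averaged -0.40 (adjusted p = 1.3e-08; adjusted p = 0.32 with an estimated correlation), with Npas4 at -0.90 and Ccn1 at -0.65, and circadian genes averaged 0.25 (adjusted p = 4.6e-05; adjusted p = 0.29 with an estimated correlation). Choroid plexus markers averaged 2.46, with 13 past the threshold when adjusted over the list alone (adjusted p = 1.1e-10; adjusted p = 0.57 with an estimated correlation). Ribosomal protein genes averaged -0.11 (adjusted p = 1.4e-05) and histone genes -0.16 (adjusted p = 0.00092), each with adjusted p = 0.68 with an estimated correlation. Of the 13 lists called in this group, these 5 kept their calls whichever array was left out. Cortical neuron markers averaged -0.35 (adjusted p = 0.011; adjusted p = 0.57 with an estimated correlation), thalamus, septum and pallidum markers 0.74 (adjusted p = 0.041; adjusted p = 0.72 with an estimated correlation) and striatal signalling genes -0.32 (adjusted p = 0.041; adjusted p = 0.73 with an estimated correlation). Without non-acupoint mouse 1 the cortical markers stood at -0.14 (adjusted p = 0.18), and without non-acupoint mouse 2 the thalamus markers stood at 0.33 (adjusted p = 0.28) and the striatal genes at -0.14 (adjusted p = 0.31). Heat shock proteins averaged 0.20 (adjusted p = 0.0047), olfactory receptor genes -0.14 (adjusted p = 4e-05) and complex I subunits -0.07 (adjusted p = 0.011), each with adjusted p = 0.72 with an estimated correlation. Without non-acupoint mouse 1 the heat shock list stood at 0.19 (adjusted p = 0.067) and the complex I list at -0.06 (adjusted p = 0.16). Reactive astrocyte genes averaged 0.22 (adjusted p = 0.021; adjusted p = 0.57 with an estimated correlation) and ependymal markers 0.21 (adjusted p = 0.019; adjusted p = 0.68 with an estimated correlation). Without non-acupoint mouse 2 these lists stood at 0.12 (adjusted p = 0.22) and 0.11 (adjusted p = 0.28), and the olfactory list at -0.02 (adjusted p = 0.22). Cables1, Scn9a and Mpp7 were higher by 0.93, 0.81 and 0.66, and Dlc1 was lower (-0.56). Limma called 0 genes in both comparisons, with 312 and 988 at an unadjusted p under 0.05. The spread that the model shares with the MPTP arrays limits these counts too.

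Both needled groups together differed from the MPTP group in ependymal markers (0.44, adjusted p = 4.8e-09) and small nucleolar RNA genes (0.17, adjusted p = 8e-04), each with adjusted p = 0.43 with an estimated correlation. Of 12 lists called, these kept their calls whichever array was left out. Striatal signalling genes went without MPTP mouse 1 from 0.41 (adjusted p = 0.014; adjusted p = 0.67 with an estimated correlation) to -0.41, the direct-pathway markers from 0.45 (adjusted p = 0.044; adjusted p = 0.67 with an estimated correlation) to -0.42, and the microglia markers from 0.11 (adjusted p = 0.023; adjusted p = 0.68 with an estimated correlation) to -0.15. Choroid plexus markers went from 0.86 (adjusted p = 0.00088; adjusted p = 0.67 with an estimated correlation) to -0.30 without MPTP mouse 2. Interneuron markers went without MPTP mouse 1 from 0.30 (adjusted p = 0.0086; adjusted p = 0.67 with an estimated correlation) to 0.06 (adjusted p = 0.36), the immediate early genes from 0.23 (adjusted p = 0.0015; adjusted p = 0.59 with an estimated correlation) to 0 (adjusted p = 0.36), and the complex I subunits from -0.11 (adjusted p = 0.00088; adjusted p = 0.67 with an estimated correlation) to -0.04 (adjusted p = 0.51). Without MPTP mouse 2 the reactive astrocyte genes went from 0.18 (adjusted p = 0.00088; adjusted p = 0.43 with an estimated correlation) to 0.12 (adjusted p = 0.24), and the heat shock proteins from 0.13 (adjusted p = 0.0056; adjusted p = 0.67 with an estimated correlation) to 0.05 (adjusted p = 0.58). Proteasome genes averaged -0.10 (adjusted p = 0.012; adjusted p = 0.43 with an estimated correlation), and stayed at -0.10 without MPTP mouse 1 (adjusted p = 0.06) or 2 (adjusted p = 0.23). Glp1r and Avpr1a were higher by 1.76 and 0.84 (adjusted p = 0.34 for each) and Eomes by 1.02 (adjusted p = 0.45), while Uqcc3 and Ccdc124 (-0.43 each) and Haghl (-0.38) were lower. With the thalamus marker covariate, chosen after seeing the data, Glp1r, Avpr1a and Eomes each had a limma adjusted p of 0.036. The thalamus marker Tnnt1 was called too (-0.89, limma adjusted p = 0.041), so the covariate may not remove all of the tissue difference. Limma called 0 genes, with 945 at an unadjusted p under 0.05, and 1541 were called without MPTP mouse 2. Across the 4 groups, the moderated F-test called 0 genes by limma, with 607 at an unadjusted p under 0.05. Its smallest p-values were those of Avpr1a, Glp1r, Sgk1, Npas4 and Eomes (adjusted p = 0.92 for each).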

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

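The tests of time of day, MPTP exposure, thalamic tissue, shared MPTP effects, tissue in MPTP mouse 1 as a source of the immediate early gene change, and ventricular lining were chosen after the results were seen; those of hypothalamus and septum markers were written beforehand, but the requirement that their values exceed their spread was added after the values were seen.

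The needled groups differed from each other in 13 gene lists by camera with a preset correlation, and in 0 with an estimated correlation (adjusted p = 0.67 for each) or by fry. Acupoint needling was higher for ribosomal protein genes (mean difference 0.12), olfactory receptor genes (0.17), histone genes (0.12), complex I subunits (0.06), small nucleolar RNA genes (0.11), striatal signalling genes (0.35), microglia markers (0.12) and glucocorticoid-responsive genes (0.08). It was lower for choroid plexus markers (-1.24), heat shock proteins (-0.24), reactive astrocyte genes (-0.17), oligodendrocyte precursor markers (-0.15) and ependymal markers (-0.19). Of the 13 calls, 4 held whichever array was left out. The choroid plexus difference was -0.14 without acupoint mouse 2, and the striatal signalling difference was -0.01 with the thalamus marker covariate. Olfactory receptor genes averaged 0.10 and -0.10 in the controls.

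Immediate early genes were lower in MPTP-treated mice than in controls, in all 6 arrays (highest list mean -0.30; exact two-sided permutation p = 0.0357, the smallest that 28 splits can give). The list was picked for this test after the values of all lists were seen, and the p-value is not corrected for that choice. Tissue from outside the striatum in MPTP mouse 1 is argued against as the whole cause, since MPTP mouse 2 alone stood at -0.36 (SE 0.09 over genes) with 21 of 25 genes below both controls, which differed by 0.018. MPTP exposure is a candidate explanation that the value of -0.30 would allow, though that value only restates the pattern. A different time of day at tissue collection cannot be told apart from it: clock output genes moved by 0.31 and 3 genes of the opposite phase by -0.02, a gap of 0.33 (exact permutation p = 0.0357 as well). As first written, that test asked only for a gap above 0.1 and would have counted in favour; the demand that the opposite phase also fall was added after the value was seen.

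MPTP mouse 1 had low medium spiny neuron genes beside high thalamus and choroid plexus genes. For an MPTP effect shared by both mice, striatal signalling genes stood at 0.26 in MPTP mouse 2, which its prediction counted against it. That prediction was written after the value was seen. MPTP mouse 2 also had the lowest mean of thalamus, septum and pallidum markers among the arrays (-0.65). The test cannot separate the dissection from such an effect, which stays open. Thalamic tissue in the dissection may account for the pattern in MPTP mouse 1. There 11 thalamus genes outside the fixed list averaged 2.01 (SE 0.29 over genes), with Slitrk6 at 3.05, Ptpn3 at 3.08 and Nexn at -0.18. In non-acupoint mouse 2 they averaged 1.29. The test written beforehand for tissue from outside the striatum used 10 hypothalamus markers and came out against it, at -0.14. That is less than its standard error of 0.17 over genes, at a mean log2 level of 6.26 and with Sim1 at 0.69 and Gpr101 at -1.27. Such an error measures how the markers differ from each other, not how mice differ. The hypothalamus test thus leaves the question open, and the thalamus test was added only after it.

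Ependymal genes were low in both MPTP mice. For an MPTP effect shared by all treated mice, the higher of the needled groups stood at 0.21, which its prediction counted against it. But acupoint mouse 1 (0.12) and non-acupoint mice 1 and 2 (0.11 and 0.32) also had high choroid plexus markers (2.32, 2.10 and 2.82). Acupoint mouse 2, at 0.13 for those markers, stood at -0.07, with the controls at 0.03 and -0.03. The test cannot separate the dissection from such an effect, which stays open. Less ventricular lining in both dissections may account for it, but its test cannot decide this. Motile cilium genes belong to the same ciliated cells, so less tissue and lower expression in those cells would both lower them. The 52 such genes outside the list had medians of -0.11 and -0.13 in the MPTP mice, but also -0.08 in acupoint mouse 2. Of these genes, 20 lay below both controls in both MPTP mice. Choroid plexus markers, of the same ventricles, stood at 2.15 in MPTP mouse 1 and -0.18 in MPTP mouse 2. Less septum stays open: its 3 markers averaged -0.41 in MPTP mouse 1 and -0.48 in MPTP mouse 2, which met the prediction as first written. In MPTP mouse 2 all 3 were lower (Nts -0.33, Zic2 -0.91 and Crhr2 -0.20). In MPTP mouse 1 their standard error over genes was 0.75 and Zic2 stood at 0.73. An MPTP effect that needling removes was not tested, and the design does not separate it from the dissection.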

How the results depend on the processing

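The settings that left out both arrays with the highest thalamus, septum and pallidum markers, or used that marker mean as a covariate, were chosen after seeing the data; the others were planned.

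Leaving out 1 array at a time moved the number of genes called from 0 to between 0 and 1607 for MPTP against control, 0 and 1453 for acupoint needling against MPTP, 0 and 794 for non-acupoint needling against MPTP, 0 and 1541 for both needled groups against MPTP, 0 and 70 for all MPTP groups against control and 0 and 518 for the F-test. The upper values came without MPTP mouse 2, and a lone array was assumed to vary like the other groups. It moved the number of lists called to between 9 and 15, 7 and 15, 8 and 16, 10 and 17 in the main comparisons in order, and to between 5 and 6 for acupoint against control, 9 and 17 for non-acupoint against control, 5 and 14 for all MPTP groups against control and 9 and 17 for both needled groups. The reversal correlation ranged from -0.94 to -0.62 for acupoint and from -0.85 to -0.18 for non-acupoint needling. Counts at an unadjusted p under 0.05 moved in every comparison, not only in the one given next. The unadjusted counts of MPTP against control ranged from 282 without control mouse 1 to 4200 without MPTP mouse 2.

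With an estimated correlation 0 lists were called in every comparison. Fry called 0 in the main comparisons and both needled groups, and 1 (the circadian list) in each of the 3 comparisons of MPTP-treated groups with control. With the marker covariate, the lists called were 8 for acupoint against control and 8 for acupoint against non-acupoint needling, and the genes called by limma were 2 for MPTP against control, 12 for non-acupoint needling against MPTP and 12 for both needled groups. Without both arrays they were 1 for acupoint against control, 2 for all MPTP groups, 2 for non-acupoint against control, 1 for both needled groups and 1 for the F-test, and 16 lists were called for MPTP against control. Array weights called 1 gene for all MPTP groups. A fit on only the groups compared called 1 gene for acupoint and 2 for non-acupoint against control. The causes were not tested.

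Without both arrays the test turned for choroid plexus (-0.183), direct-pathway (0.32), striatal signalling (0.264), microglia (0.097) and interneuron (0.025) markers in MPTP against control, for ribosomal (-0.029), direct-pathway (-0.276), striatal signalling (-0.231), indirect-pathway (-0.231), microglia (-0.089) and interneuron (0.035) lists in acupoint needling against MPTP, and for olfactory (0.054) and interneuron (0.093) lists in non-acupoint needling against MPTP. Interneuron means kept their sign where only the test against other genes turned. The reversal correlation of non-acupoint needling was -0.67 without both arrays. With a different MPTP mouse in each change the reversal correlations turned to 0.40 and 0.30 for acupoint and to 0.53 and 0.19 for non-acupoint needling. The MPTP mice lay on opposite sides of the controls on the first principal component, which could account for this and was not tested. Fos in acupoint needling against MPTP turned to 0.01 with median centring, 0.003 with quantile normalisation and 0.015 with the covariate. Among named genes, 2748 values outside the leave-one-out fits kept their direction and side of the threshold, while 11 became called and 3 turned. No named gene was called in the main fits, so no call could be lost, and the count is no measure of robustness. The mouse number does not pair the samples: same-numbered mice had correlations of deviations between -0.49 and 0.40. With it as a replicate block, which leaves 3 residual degrees of freedom, limma called 0 genes in every comparison.

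Leaving out 1 array at a time turned 46 gene values and, in the main comparisons, 15 list values. For both needled groups against MPTP, 4 of the 12 lists called turned without MPTP mouse 1 and 1 without MPTP mouse 2. For lists the direction is that of the test against other genes, which turned for interneuron markers in both comparisons of needling with MPTP and for histone genes in the non-acupoint one while their means kept their sign. In MPTP against control, the direction turned in at least 1 such fit, with these ranges: choroid plexus markers (-0.18 to 2.15), direct-pathway medium spiny neuron markers (-1.42 to 0.32), dopamine receptors and striatal signalling (-1.37 to 0.26), Drd1 (-2.38 to 0.37), Drd2 (-1.93 to 0.46), Gfap (-0.57 to 0.14), Isl1 (-1.12 to 0.065), Kcnj13 (-0.33 to 4.74), Lhx6 (-0.76 to 0.015), microglia markers (-0.41 to 0.097), Pdyn (-1.75 to 0.63), Penk (-1.81 to 0.18), Ppp1r1b (-2.40 to 0.28), Rgs2 (-1.46 to 0.049), Rgs9 (-2.38 to 0.35), Slc18a3 (-1.18 to 0.097), Slc35d3 (-1.51 to 0.28), Slc5a7 (-2.41 to 0.11), striatal interneuron markers (-0.45 to 0.025), Tac1 (-2.54 to 0.40), Th (-0.11 to 0.33), Tmem72 (-0.009 to 1.19), Ttr (-0.64 to 4.63). In acupoint needling against MPTP, the direction turned in at least 1 such fit, with these ranges: cytosolic ribosomal protein genes (-0.029 to 0.11), direct-pathway medium spiny neuron markers (-0.28 to 1.46), dopamine receptors and striatal signalling (-0.23 to 1.40), Drd1 (-0.39 to 2.36), Drd2 (-0.36 to 2.03), Fos (-0.28 to 0.24), Gfap (-0.15 to 0.56), Gpr52 (-0.36 to 2.31), indirect-pathway medium spiny neuron markers (-0.23 to 1.22), Isl1 (-0.13 to 1.05), Lhx8 (-0.060 to 0.86), microglia markers (-0.089 to 0.42), olfactory receptor genes (-0.026 to 0.17), P2ry12 (-0.034 to 0.55), Pde10a (-0.26 to 2.09), Pdyn (-0.39 to 1.99), Penk (-0.10 to 1.88), Ppp1r1b (-0.27 to 2.41), Rasd2 (-0.005 to 2.07), Slc18a3 (-0.16 to 1.11), Slc35d3 (-0.28 to 1.51), Slc5a7 (-0.18 to 2.35), Slc6a3 (-0.62 to 0.35), Sst (-0.12 to 1.29), striatal interneuron markers (0.035 to 0.51), Tac1 (-0.20 to 2.74), Th (-0.23 to 0.48), Ttr (-1.69 to 3.58). In non-acupoint needling against MPTP, the direction turned in at least 1 such fit, with these ranges: histone genes (-0.27 to -0.009), Lhx8 (-0.015 to 0.91), Nr4a1 (-0.047 to 1.76), olfactory receptor genes (-0.22 to 0.014), Slc18a3 (-0.031 to 1.25), striatal interneuron markers (0.095 to 0.57).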

Other observations

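The tests below were chosen after the results were seen, except the count of partitions, which was planned; the share at which it would stand out was set afterwards.

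A pair of probe sets without a gene name fell far below the controls in every MPTP-treated mouse. They were found among 13768 probe sets with no gene or several genes, which were fitted on their own after their values were seen, without the filter on dim probe sets. Probe set 10598075 had log2 values of 7.01 and 7.47 in controls, 3.88 and 3.49 in MPTP mice, 3.95 and 4.09 after acupoint needling and 2.83 and 2.65 after non-acupoint needling. By limma the adjusted p against control was 0.026 for MPTP mice, 0.049 for the acupoint group, 0.006 for the non-acupoint group and 0.0052 for all MPTP-treated mice. Probe set 10598077 had 6.15 and 6.92 in controls and between 3.13 and 3.97 in the MPTP-treated arrays, with a limma adjusted p of 0.031 for all MPTP-treated mice. Their means over the 8 arrays were 4.42 and 4.16, below the 5.25 asked of the 16342 probe sets of the main comparisons. All their values in MPTP-treated arrays lie below that level, so no size of change is given, and the p-values are not comparable with those of the report. What these probe sets measure is not analysed here.

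The grouping of the arrays did not stand out among other groupings. The F-test over the 4 groups gave 607 probe sets at an unadjusted p under 0.05, and 37 of 100 partitions of the arrays into 4 pairs gave as many, so chance is not excluded. The highest other count was 3112, with 467 past the adjusted threshold. That partition paired the controls, MPTP mouse 1 with non-acupoint mouse 2, MPTP mouse 2 with acupoint mouse 2, and acupoint mouse 1 with non-acupoint mouse 1. It was picked as the highest, and what such a highest count means was not tested.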
